A study of Lactococcus lactis with 15 samples.

How the data were processed

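Gene expression was measured in 15 samples of Lactococcus lactis with 1-colour Agilent arrays. Per the labels' protocols, total RNA was extracted with hot phenol, 5 µg was turned into Cy3-labelled cDNA, and 1 sample was hybridised per array. Per the file headers, the spots were read with Agilent Feature Extraction 10.5.1.1, whereas the submitters' processing notes name version 9.1. Samples were put in 4 groups by strain and temperature as the labels give them.

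The deposited scanner files hold intensity values of 13878 spots per array, 1 spot per probe, and 13342 of these are not controls. The processed signal is a background-subtracted intensity, per the file headers, with low values replaced by a surrogate, and it is not normalized between arrays. The median spot signal and its local background are deposited as intensities without correction. The authors' value table gives 1 value per probe and array on what looks like a log2 scale. Its columns had medians of 13.05 to 13.06 and ranked the probes exactly as that array's median signal did (Spearman 1). Differences between its arrays correlated with r of 0.995 to 0.998 with those of quantile-normalized log2 median signals. By this comparison the deposited log2 values appear quantile-normalized and not centred per gene or background-subtracted, although the sources used here do not state the steps.

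For the main results, log2 of the processed signal minus the log2 of the array's 75th percentile was used. Spots marked as non-uniform or population outliers were left out. A gene's value on an array was the least squares mean over its probes, fitted with probe and array terms, which equals the plain mean where no spot was missing. Probes named for pseudogenes (404), rRNA (581), tRNA (231) and 5 further probes stayed out of the gene tests. A gene was to be kept if at least 1 probe was well above background on 3 or more arrays, and 0 of 2434 genes were removed. Below, a gene is described as above background on an array where at least 1 of its probes was well above it. Where none was, it is described as below background.

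All 15 arrays were fitted with 1 mean per group in limma 3.58.1 under R 4.3.3, with lmFit and eBayes (11 residual and 3.02 prior degrees of freedom), and p-values were adjusted by Benjamini-Hochberg over 2434 genes. A gene was called at an adjusted p under 0.05. The comparisons were CS3527 against MG1363 at each temperature and over both, 38 °C against 30 °C in each strain, and the interaction. Differences are on the log2 scale, and fold is 2 to the power of that difference. Where all probes of a gene were below background on every array of a group, the fold is a lower bound against the higher of the probe's own signal and the lowest signal well above background on that array. Probe classes were compared by exact permutation of array medians. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

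The scan and the slide separate the temperatures completely. A block for slide is thus contained in the group means of the strain comparisons, and an additive slide effect cancels in the interaction. The number of arrays limits the precision. The fit was tested on simulated arrays of 2434 genes with 200 changed. For the strain comparison at 38 °C it recovered 56.7% of genes changed by 0.5 on the log2 scale, 89.6% of those changed by 1 and 98.5% of those changed by 2, with 13 false calls among 2234 unchanged genes. For the interaction the shares were 43.3%, 77.6% and 100%, with 3 false calls. The simulated noise was independent between genes and equal in all groups. These figures thus leave out array-wide deviations and shared changes of neighbouring genes.

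Before the data were examined, the comparisons, the rule for named genes and most alternatives were fixed. The rule named the 8 genes with the largest rise and fall per comparison, with groups that do not overlap, and 6 for the interaction. It was reduced to the first 2 per direction because the files pair no locus tag with a gene name: 0 of 2434 locus tags matched the reference table at hand, which describes another strain. For the same reason none of the 29 gene lists planned, nor genes of glycolysis or heat shock by name, could be tested. Regions were chosen after the data were seen, as the 2 longest runs of neighbouring genes called and at least 2-fold changed per direction and comparison, and for the interaction and the closing section by their values. The region llmg_0835 to llmg_0851 entered through the temperature comparison in CS3527. Neighbours are successive locus tag numbers, taken as genome order, and no genome coordinates were used here. Runs of at least 4 were compared with 1000 shuffles of the gene order.

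Alternatives were quantile and median scaling, normexp background correction (offset 50, on the median signal because the files lack a mean signal), the authors' values, no filter, a filter keeping 2162 genes above background on all 15 arrays, the median over probes, a variance trend with robust fit, fits of the compared groups alone, array weights, a replicate block, leaving out each array, and a 2-fold threshold. A common floor under dim signals, keeping marked spots and the alternatives for probe classes were added after the data were seen. The floor was the highest, over arrays, of the lowest signal well above background relative to the 75th percentile. The dimmest array, CS3527 at 30 °C replicate 1, alone set it, with a lowest such signal of 227.1 at a 75th percentile of 9768.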

Results

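Transcript levels were measured in Lactococcus lactis, a lactic acid bacterium of milk fermentation, in strain MG1363, a plasmid-free laboratory strain, and in CS3527. The series title calls CS3527 a mutant for high temperature. Each strain was grown at 30 °C and at 38 °C in a defined medium with 0.2% glucose and sampled in exponential growth at an OD600 of 0.3. MG1363 at 30 °C, CS3527 at 30 °C and CS3527 at 38 °C had 4 arrays each, and MG1363 at 38 °C had 3, which makes 15 arrays of 1 colour. The labels number the replicates but do not say that they came from separate cultures. The p-values therefore measure the spread between these samples, which may be technical. On each array 12121 probes covered 2434 protein-coding locus tags, 2401 of them with 5 probes.

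All 8 arrays at 30 °C lay on slide 1 and all 7 arrays at 38 °C on slide 2, so temperature and slide cannot be told apart, while the strains can be compared within each slide. On both slides the strains also lay in different rows of arrays, so a row effect and a strain difference cannot be told apart either. The 75th percentile of the probe signal ran from 9768 to 27554 on slide 1 and from 35562 to 47223 on slide 2. Between 81.0% and 95.2% of the probes were well above background on slide 1 and between 89.6% and 99.1% on slide 2. The dimmest array was CS3527 at 30 °C replicate 1. Across genes, which are not independent replicates, arrays of one group correlated with Pearson r of 0.977 to 0.998. The files give locus tags without gene names or products, so genes are given by locus tag, with at most 2 higher and 2 lower per comparison, and neighbouring genes are described as regions from the first to the last tag.

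The first comparison asked how CS3527 differed from MG1363 at 38 °C. A block of 10 neighbouring genes, llmg_1349 to llmg_1358, was far lower in CS3527. Its mean log2 signal was 1.07 ± 0.04 (SD, n = 3) in MG1363 and -4.24 ± 0.10 (SD, n = 4) in CS3527, a 39.7-fold difference. All 10 genes fell, as the choice of regions required, by log2 differences between -5.53 and -5.10. The genes on either side were lower by far less, llmg_1348 with a difference of -0.48 and llmg_1359 with -0.46. At least 49 of the block's 50 probes stayed well above background on each CS3527 array at both temperatures.

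Other regions of neighbouring genes moved less at 38 °C. The 8 genes of llmg_0738 to llmg_0745 were lower in CS3527, with a mean of -5.74 ± 0.07 (SD, n = 3) in MG1363 and -7.04 ± 0.16 (SD, n = 4) in CS3527. The 7 genes of llmg_2402 to llmg_2408 were higher, with means of -6.61 ± 0.05 (SD, n = 3) and -5.01 ± 0.07 (SD, n = 4). The 5 genes of llmg_2219 to llmg_2223 were higher by a mean log2 difference of 1.10. Every gene of these 3 regions was called, which the choice of regions required. Of single genes, llmg_1195 rose most in CS3527, 5.19-fold (log2 difference 2.38, SE 0.10, limma adjusted p = 1.66e-10), followed by llmg_1993, 4.20-fold (2.07, SE 0.14). The largest falls were those of llmg_1358, 46.1-fold (-5.53, SE 0.11, limma adjusted p = 5.09e-14), and llmg_1357, 43.8-fold (-5.45, SE 0.15), both in the block.

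At an adjusted p under 0.05 the limma fit called 1132 of 2434 genes at 38 °C, 543 higher and 589 lower in CS3527. The share of higher calls, 48.0%, passed 50% under other scalings, with 57.8% under median scaling, 52.8% under quantile scaling and 53.3% with the authors' values, so no excess in either direction is read from it. Most differences were small, since 85 genes were at least 2-fold higher and 123 at least 2-fold lower. With a common floor under dim signals, the mean difference of llmg_0738 to llmg_0745 went from -1.30 to -0.31 and that of llmg_2402 to llmg_2408 from 1.60 to 0.58. The floor, at -5.43, lay above both strains' means of the former and above the MG1363 mean of the latter. It thus shrinks both differences by construction. Under the other scalings without a floor they ran from -1.22 to -0.89 and from 1.35 to 1.76.

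At 30 °C the same comparison gave the same block and additional regions. The block llmg_1349 to llmg_1358 had a mean of 1.15 ± 0.12 (SD, n = 4) in MG1363 and -3.81 ± 0.20 (SD, n = 4) in CS3527, 31.0-fold lower, and all 10 genes fell. The 9 genes of llmg_1089 to llmg_1097 were also lower, with means of -1.79 ± 0.07 (SD, n = 4) and -3.53 ± 0.14 (SD, n = 4), or 3.35-fold. The longest region higher in CS3527 held 35 genes, llmg_1371 to llmg_1411. Its mean was -5.93 ± 0.11 (SD, n = 4) in MG1363 and -3.64 ± 0.20 (SD, n = 4) in CS3527, 4.89-fold, and all 35 genes rose. The choice of regions required the genes of each to move in the same direction.

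A further region higher at 30 °C was llmg_0802 to llmg_0821, whose 19 genes all rose, as its choice required, with means of -8.17 ± 0.18 (SD, n = 4) and -6.16 ± 0.26 (SD, n = 4). Close to it, the 16 genes of llmg_0835 to llmg_0851 rose from -8.59 ± 0.11 (SD, n = 4) in MG1363 to -5.46 ± 0.28 (SD, n = 4) in CS3527. Beside and between them, the runs llmg_0795 to llmg_0800 and llmg_0824 to llmg_0831 were also higher, by means of 2.66 and 2.46. These regions may thus not be independent of each other. Of single genes, llmg_0838 was higher by a fitted 11.7-fold (log2 difference 3.54, SE 0.20, limma adjusted p = 1.92e-09), measured above background on 2 of the 4 MG1363 arrays. None of the probes of llmg_0835 was well above background on the 4 MG1363 arrays. Under 75th percentile scaling it was at least 5.94-fold higher in CS3527 (limma adjusted p = 2.15e-07), a bound that gives it no rank against llmg_0838. The largest falls were those of llmg_1349, 34.8-fold (-5.12, SE 0.13), and llmg_1356, 34.2-fold (-5.10, SE 0.10).

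At 30 °C 1448 genes were called, 854 higher and 594 lower in CS3527, with 250 at least 2-fold higher and 151 at least 2-fold lower. The share of higher calls was 59.0%, and 62.7% under median scaling and 59.8% under normexp. It was 50.7% under quantile scaling and 50.5% with the authors' values, which appear quantile-normalized. Quantile scaling gives all arrays one distribution and so largely evens this share by construction. The last values thus do not tell whether the excess is technical. Sizes for dim regions depended on the scaling. The mean difference was 3.13 for llmg_0835 to llmg_0851 and ran from 1.71 to 3.17 under the other scalings without a floor, and it was 2.01 for llmg_0802 to llmg_0821 with a range of 1.02 to 2.05. A common floor, which at -5.43 lies above every group mean of both regions, left 0.37 and 0.14 and so decides nothing for them. The bound for llmg_0835 did not hold under every scaling, since its log2 difference was 2.12 under normexp, 2.47 with the authors' values and 0.51 with the floor, and that of llmg_0838 was 1.91, 2.16 and 0.34.

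**Figure D1:**
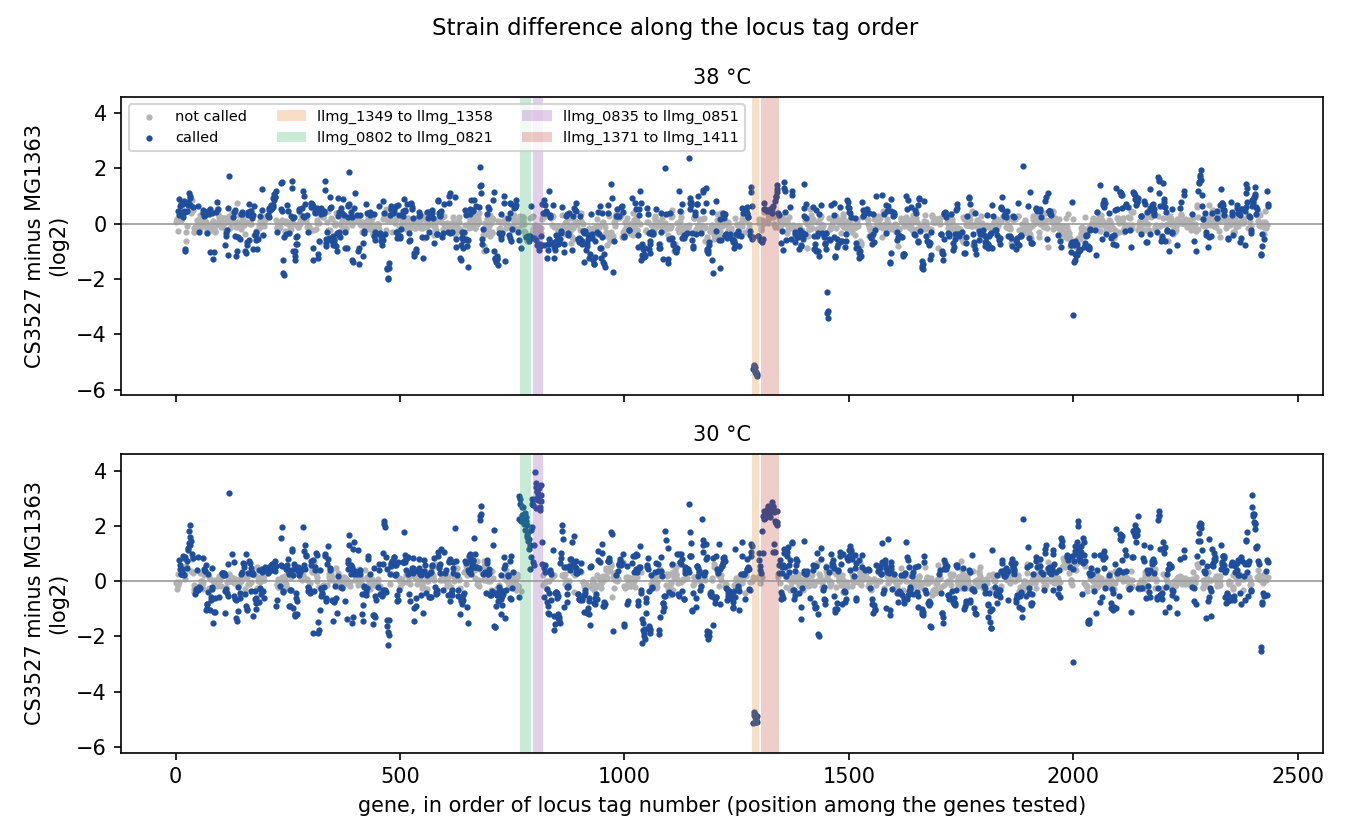
The log2 difference between CS3527 and MG1363 (vertical axis) of each of the 2434 genes in the order of their locus tag numbers (horizontal axis), at 38 °C in the upper panel and 30 °C in the lower, with called genes in blue. The block llmg_1349 to llmg_1358 lies near -5 in both panels, and llmg_0802 to llmg_0821, llmg_0835 to llmg_0851 and llmg_1371 to llmg_1411 lie well above 0 at 30 °C.

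Neighbouring genes were called in the same direction more often than shuffled gene orders gave. At 38 °C 82 runs of at least 4 neighbours occurred, the longest of 19 genes, against a median of 11 runs in 1000 shuffles and a longest shuffled run of 11. At 30 °C 115 runs occurred, the longest of 47 genes, against a median of 30 runs and a longest shuffled run of 15. In both cases no shuffle reached the observed values, and the permutation p of 0.000999 is the smallest that 1000 shuffles can give. Neighbours in one operon share a transcript, so genes are not independent.

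The strain differences at both temperatures were then set side by side. Of the genes called at both, 814 differed in the same direction and 56 in opposite directions. There were 431 genes higher in CS3527 at both temperatures, where independent lists of these lengths would share 190.5, and 383 lower at both, where 143.7 would be shared. Across genes the log2 differences correlated with Pearson r of 0.65 and Spearman rho of 0.60, and the comparisons share no arrays. Averaged over both temperatures, with the slides so balanced, 1526 genes were called, 838 higher and 688 lower. No gene was below background on all arrays of one strain and above it on all arrays of the other at both temperatures. At 30 °C alone, 4 genes were below background on all MG1363 arrays and above it on all CS3527 arrays.

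**Figure D2:**
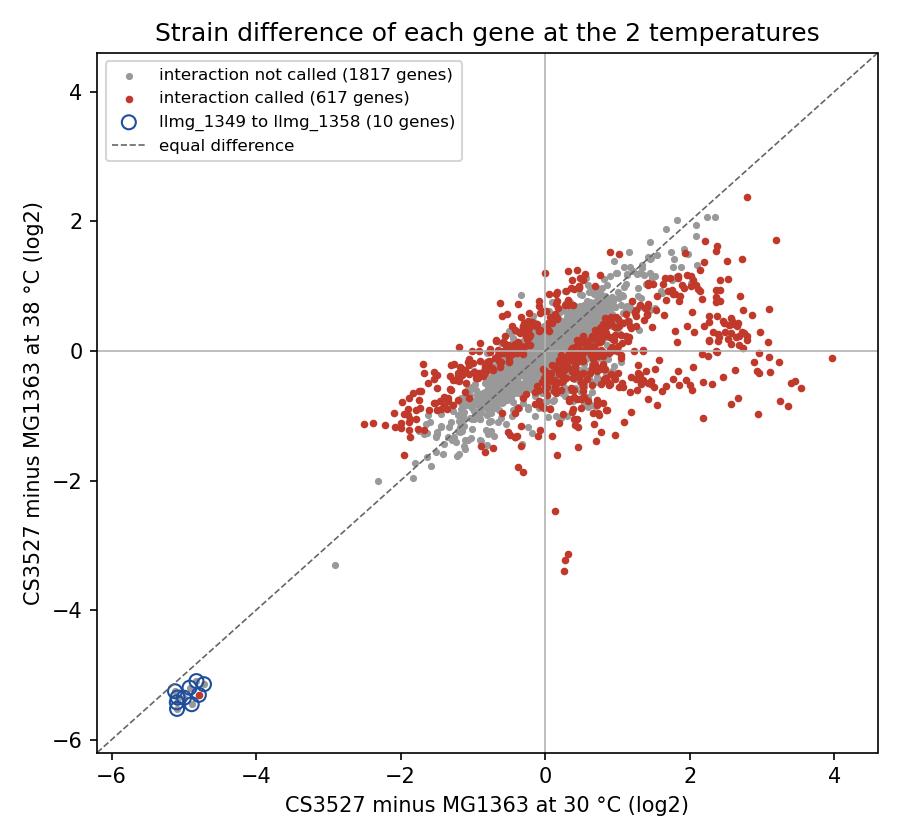
Log2 difference between CS3527 and MG1363 at 30 °C (horizontal axis) and at 38 °C (vertical axis), 1 point per gene, with the 617 genes of a called interaction in red and the genes llmg_1349 to llmg_1358 circled. The circled genes lie near -5 on both axes, and many red points lie to the right with little difference at 38 °C.

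The interaction asked which strain differences changed with temperature, that is the difference at 38 °C minus that at 30 °C. Of the regions higher in CS3527 at 30 °C, 3 that were chosen by their values differed much less between strains at 38 °C. For llmg_0835 to llmg_0851 the interaction mean was -3.58, and all 16 genes were called. All 19 genes of llmg_0802 to llmg_0821 were called with a mean of -2.30, and all 35 of llmg_1371 to llmg_1411 with -1.86. In CS3527 at 38 °C these regions had means of -8.93 ± 0.27, -7.19 ± 0.32 and -6.86 ± 0.22 (SD, n = 4), against -8.49 ± 0.13, -6.90 ± 0.09 and -7.30 ± 0.07 (SD, n = 3) in MG1363. Other regions stayed higher at 38 °C: llmg_2402 to llmg_2408 had 1.82 at 30 °C and 1.60 at 38 °C, with 0 genes called in the interaction, and llmg_2219 to llmg_2223 had 1.61 and 1.10, with 4 called. The block llmg_1349 to llmg_1358 had an interaction mean of -0.36, with 1 of its 10 genes called, and -0.88 under quantile scaling. The interaction mean of llmg_0835 to llmg_0851 was -1.94 under normexp, -1.93 with the authors' values and -0.37 with the common floor, and that of llmg_0802 to llmg_0821 was -1.20, -1.05 and -0.15.

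Negative interactions were fitted for llmg_0845 (-4.22, SE 0.37, limma adjusted p = 2.09e-06) and llmg_0838 (-4.12, SE 0.29, limma adjusted p = 3.29e-07). Of the 4 arrays each, llmg_0845 was above background on 1 MG1363 array at 30 °C and 2 CS3527 arrays at 38 °C, and its call was lost under the common floor (-0.15). On those arrays llmg_0838 was above background on 2 and 1, and its interaction was -2.23 under normexp and -0.34 with the floor. In the opposite direction, llmg_1917 had 1.50 (SE 0.17) and llmg_2547 had 1.39 (SE 0.10), the strain difference of llmg_1917 going from -1.69 at 30 °C to -0.20 at 38 °C and that of llmg_2547 from -2.51 to -1.12. In all, 617 genes had a called interaction, 205 positive and 412 negative. Among them 447 had the larger strain difference at 30 °C. The share of positive calls was 33.2%, and 37.4% under median scaling and 31.7% under normexp. It moved to 54.8% under quantile scaling and to 53.8% with the authors' values. Quantile scaling largely evens this share by construction, so these last values do not tell whether the excess is technical.

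**Figure D3:**
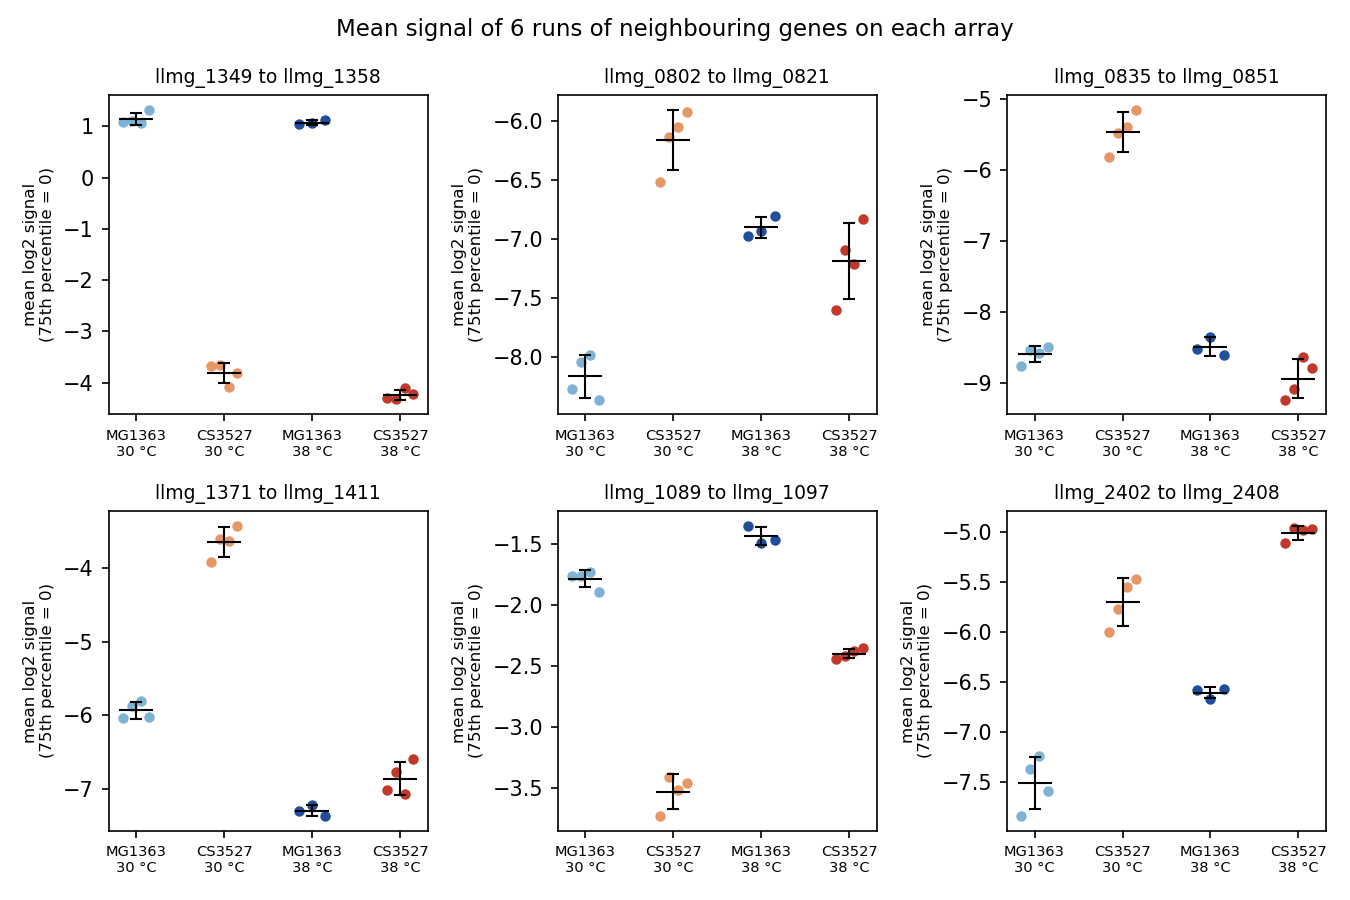
Mean log2 signal relative to the array's 75th percentile (vertical axis) of 6 runs of neighbouring genes, 1 point per array, for both strains at 30 °C and 38 °C, with the group mean and its SD as a bar. In llmg_0835 to llmg_0851 the CS3527 arrays at 30 °C stand above all other arrays, with a mean of -5.46, and in llmg_1349 to llmg_1358 all CS3527 arrays lie below -3.

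The temperature comparisons asked how each strain at 38 °C differed from itself at 30 °C, and both carry the difference between the slides. In MG1363 the 15 genes of llmg_0026 to llmg_0040 were higher at 38 °C, with means of -7.55 ± 0.12 (SD, n = 4) at 30 °C and -5.85 ± 0.09 (SD, n = 3) at 38 °C. The 13 genes of llmg_2249 to llmg_2261 were also higher, with means of -7.76 ± 0.22 (SD, n = 4) and -5.73 ± 0.09 (SD, n = 3). Lower at 38 °C were the 22 genes of llmg_1375 to llmg_1398, by a mean log2 difference of -1.71, and the 6 genes of llmg_1406 to llmg_1411, by -1.67. Every gene of these 4 regions was called in MG1363, which the choice of regions required.

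The largest single rises in MG1363 were those of llmg_0487, 25.9-fold (log2 difference 4.69, SE 0.13, limma adjusted p = 1.64e-12), and llmg_0488, 24.4-fold (4.61, SE 0.12). Their log2 differences were 4.01 and 3.73 with the authors' values and 4.41 and 3.67 with the common floor. The largest falls were those of llmg_0910, 8.32-fold (-3.06, SE 0.17, limma adjusted p = 4.15e-09), and llmg_1104, 7.18-fold (-2.84, SE 0.09). In all, 1656 genes were called, 1122 higher and 534 lower at 38 °C. The share of higher calls was 67.8%, but it was 52.3% under quantile scaling, 47.6% under median scaling and 53.6% with the authors' values. Quantile scaling largely evens this share by construction. The mean of llmg_0026 to llmg_0040 moved from 1.69 to 0.54 under normexp and 0.88 under quantile scaling. That of llmg_2249 to llmg_2261 moved from 2.03 to 0.82 and 1.26. The falls of llmg_1375 to llmg_1398 and llmg_1406 to llmg_1411 were larger under quantile scaling, -2.56 and -2.46, and were -1.53 and -1.55 under normexp. With a common floor, which lies above their means in MG1363, the 4 regions had 0.32, 0.28, -0.11 and -0.28.

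In CS3527 the same pair of genes rose at 38 °C, with fitted log2 differences of 5.01 for llmg_0487 (SE 0.12, limma adjusted p = 3.44e-13) and 4.47 for llmg_0488 (SE 0.11). At 30 °C they were above background on 1 and 3 of the 4 CS3527 arrays, so these sizes are uncertain, and they were 3.43 and 2.92 under normexp. The gene llmg_1397 fell 24.3-fold (-4.60, SE 0.14, limma adjusted p = 2.37e-12). For llmg_0839, above background on 1 of 4 arrays at 38 °C, the fitted difference was -4.45 (SE 0.27), with -3.12 under normexp and -2.85 with the authors' values. The 23 genes of llmg_1375 to llmg_1399 fell by a mean log2 difference of -3.74 and the 16 genes of llmg_0835 to llmg_0851 by -3.47. Higher at 38 °C were the 9 genes of llmg_1091 to llmg_1099, by a mean of 1.27, and the 8 genes of llmg_1454 to llmg_1461, by 1.56. The latter came to 0.60 under normexp, and with a common floor it was 0.18, llmg_1375 to llmg_1399 had -1.77 and llmg_0835 to llmg_0851 had -0.38. The floor lay above the CS3527 means of llmg_1454 to llmg_1461 and llmg_0835 to llmg_0851 at both temperatures. For llmg_1375 to llmg_1399 it lay above that at 38 °C. It thus shrinks these differences by construction. Of the genes, llmg_0487 then rose by 2.43 and llmg_0488 by 2.12, and llmg_1397 and llmg_0839 had -2.51 and -0.34.

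In CS3527 1419 genes were called between temperatures, 901 higher and 518 lower. The share of higher calls was 63.5%, but 41.5% under median scaling and 51.8% under normexp. Of genes called in both strains, 1079 moved the same way with temperature and 78 in opposite ways, and across genes the differences correlated with Pearson r of 0.67. Both comparisons span the same slides, so a slide effect would enter this correlation too.

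Ribosomal and transfer RNA probes had lower means at 38 °C relative to the array's 75th percentile, in differences that did not pass correction. The median of 581 rRNA probes was 4.45 ± 0.27 (SD, n = 4) at 30 °C and 3.70 ± 0.22 (SD, n = 3) at 38 °C in MG1363, and 4.46 ± 0.57 and 3.81 ± 0.18 (SD, n = 4) in CS3527. The median of 231 tRNA probes differed by -1.07 in MG1363 and by -0.83 in CS3527. Each of these 4 comparisons had an exact two-sided permutation p of 0.0286, or 0.0571 after adjustment over 12 comparisons of probe classes. In each, every array at 30 °C lay above every array at 38 °C, which were also on different slides. The unadjusted p is the smallest these group sizes allow, so the adjustment left little room to pass and its outcome is no evidence of equal levels. Without CS3527 at 30 °C replicate 1, whose rRNA median was 5.31, the rRNA difference in CS3527 went from -0.65 to -0.36. Under quantile scaling and with the authors' values the rRNA difference was 0, since the median of these probes fell on the same normalized value on every array.

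Differences also varied with signal, in the strain comparisons as well as with temperature. At 30 °C the median log2 difference between CS3527 and MG1363 was 0.59 in the dimmest of 5 equal groups of genes and 0.04 in the brightest, and -0.02 and 0.03 under quantile scaling. At 38 °C the trend was opposite, with -0.27 in the dimmest group and 0.07 in the brightest, and -0.02 and 0.02 under quantile scaling. Such opposite trends push the interaction of dim genes down under the main scaling. All 19 genes of llmg_0802 to llmg_0821, all 16 of llmg_0835 to llmg_0851 and 30 of the 35 of llmg_1371 to llmg_1411 lay in the dimmest group. In MG1363 the median temperature difference was 0.90 in the dimmest group and -0.23 in the brightest, and under quantile scaling these medians were 0.02 and -0.01. Quantile scaling gives all arrays one distribution and so flattens such trends whatever their cause. Its values thus do not tell whether the trends are technical.

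**Figure D4:**
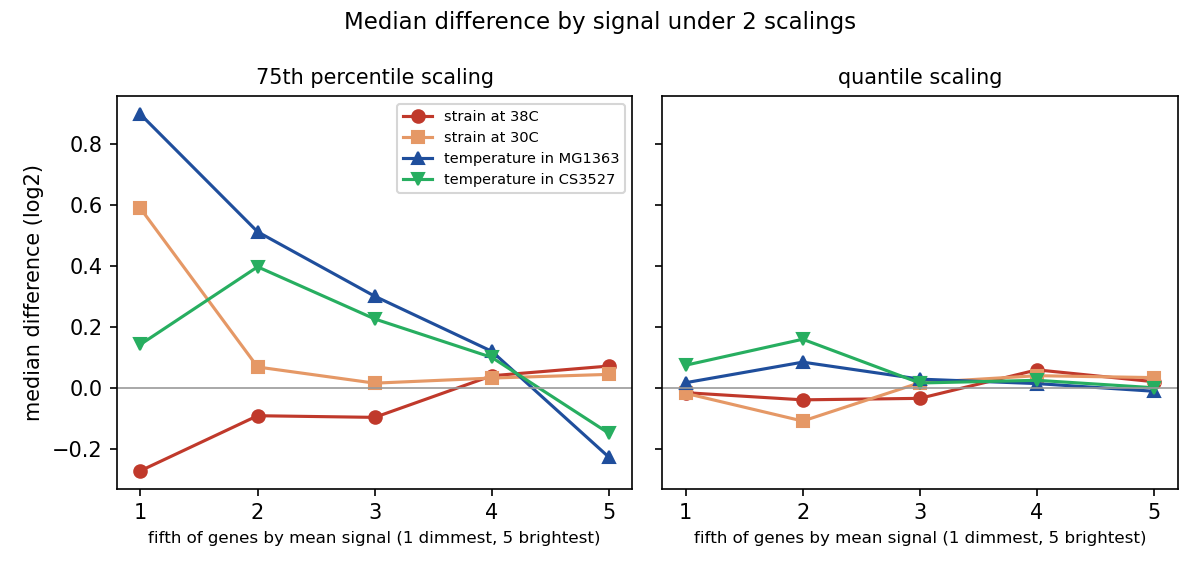
Median log2 difference (vertical axis) of the genes in each of 5 equal groups by mean signal (horizontal axis, dimmest to brightest) for the strain and temperature comparisons, under 75th percentile scaling at left and quantile scaling at right. The temperature difference in MG1363 goes from 0.90 in the dimmest group to -0.23 in the brightest at left and stays between -0.01 and 0.08 at right. Quantile scaling flattens such trends by construction.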

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

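The count of the block's probes at least 8-fold lower, the test with arrays left out, the signal trend with temperature, and the checks of the dimmer regions under other scalings were chosen after the result was seen, while the counts of other splits and the remaining tests were set before.

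The numbers of called genes were compared with those from other splits of the arrays. At 38 °C 1132 genes separated the strains and the highest of the other 34 splits gave 501. At 30 °C the counts were 1448 and 66. Between temperatures, MG1363 gave 1656 and at most 1273 in another split, which set 3 arrays of 30 °C against the rest and so still parted mostly by temperature. CS3527 gave 1419 and at most 28. In each of these comparisons the real split alone, 1 of 35, reached its count, the smallest share that 35 splits allow. In 100 drawn assignments of strain within slides, the contrast over both temperatures gave 1526 and at most 808, so 1 of 100 reached it. For the interaction 3 of 100 assignments, the real one included, reached 617, the highest with 771. Both exceeding draws kept every strain label on one slide. The highest mixed the strains nearly evenly at 38 °C, so it measured mainly the strain difference at 30 °C, and the other, with 720 genes, exchanged most labels at 30 °C. Such draws hold strain differences themselves, so for the interaction these counts do not tell whether chance gives 617.

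The interaction called 617 genes whose strain difference changed with temperature. Of the genes named in the report, 4 in llmg_0835 to llmg_0851 had fitted values of -4.07 for llmg_0835, -4.12 for llmg_0838, -3.90 for llmg_0839 and -4.22 for llmg_0845. Each was below background on part or all of the arrays of MG1363 at 30 °C and of CS3527 at 38 °C, so these sizes have no order, and with the common floor llmg_0838 had -0.34 and llmg_0845 -0.15. In llmg_1397 it was -2.10 and in llmg_1195 -0.42. Positive values were found for llmg_1917 (1.50), llmg_2547 (1.39) and llmg_0910 (0.74).

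The block llmg_1349 to llmg_1358 was 31.0-fold and 39.7-fold lower in CS3527. Sequence differences under single probes are argued against, since 50 of 50 probes were at least 8-fold lower at both temperatures. Unrelated transcripts binding these probes are argued against as well, since the signal left in CS3527 followed that in MG1363 across probes with a Pearson r of 0.98. Transcripts of similar sequence could follow the same probe pattern, so this value does not test them. A loss of the segment with some MG1363 RNA in each CS3527 sample stays open, since the 10 genes fell nearly alike within an array (widest range 0.69 log2 units) and stood at 2.38% to 3.60% of the MG1363 level. Much lower transcription of the whole block may be the biological reading, and no value here separates them.

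The regions llmg_0802 to llmg_0821, llmg_0835 to llmg_0851 and llmg_1371 to llmg_1411 were higher in CS3527 at 30 °C, with a much smaller or opposite difference at 38 °C. A single deviating array is argued against, since the interaction mean closest to 0 among the regions was -1.78 with any array left out. Signal-dependent array differences are argued against as the whole cause where the interaction mean stayed below -1 by more than its SE, which held for llmg_1371 to llmg_1411 (closest to 0 under quantile scaling with -1.33, SE 0.08, among quantile scaling, normexp and the authors' values) and for llmg_0835 to llmg_0851 (closest to 0 with the authors' values at -1.93, SE 0.09). For llmg_0802 to llmg_0821 they stay open, since the mean closest to 0 was -1.05 with the authors' values (SE 0.11). The common floor at -5.43 lay above every group mean of llmg_0802 to llmg_0821 and llmg_0835 to llmg_0851 and decides nothing for them. For llmg_1371 to llmg_1411 the test as first set had counted the floor, which gave -1.55 (SE 0.09) and a strain difference of 1.56 at 30 °C. There the floor lay above both strains' means at 38 °C, so it was later left out. A response to temperature that differs between the strains may be the biological reading.

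More genes were called higher than lower at 38 °C under the main scaling, 67.8% in MG1363 and 63.5% in CS3527, but median scaling turned this to 47.6% and 41.5%. Quantile scaling, which largely evens these shares by construction, gave 52.3% and 56.4%. The dimmest of 5 equal groups of genes exceeded the brightest in the median temperature difference by 1.13 in MG1363 and by 0.29 in CS3527, the smaller value lying between the bounds set for slide and scan brightness. Slide and temperature cannot be told apart here, so brightness and growth temperature both may contribute.

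Of 120 groups of 4 arrays examined for a single distant array, 6 held one, which is the number that chance gives at 1 in 20 if the groups are independent. They are not, since they reuse the same arrays and several regions overlap or hold the named genes. The number thus does not tell whether the flags arose by chance. The median rRNA signal of CS3527 at 30 °C replicate 1 was 5.31 and that of its other replicates 4.12 to 4.20. This was also the dimmest array, and it had the lowest array weight, 0.12. In that array llmg_1917 was at -2.29. In MG1363 at 30 °C replicate 4 the mean of llmg_1349 to llmg_1358 was 1.33 and llmg_1356 was at 1.03. In CS3527 at 38 °C the mean of llmg_2402 to llmg_2408 was -5.11 in replicate 1 and llmg_1349 was at -6.23 in replicate 2.

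Outside the gene tests, the median of the 5 probes not named for a locus tag was higher in CS3527 than in MG1363 at 30 °C by 2.05 on the log2 scale. The means were -4.89 ± 0.39 and -6.94 ± 0.48 (SD, n = 4), with an exact two-sided permutation p of 0.0286, the smallest that 70 splits allow in both directions. This p was not adjusted, and the same permutation p in the other probe classes was 0.0571 after adjustment. The difference was 1.66 under quantile scaling, 1.46 under normexp and 1.39 with the authors' values. At 38 °C the difference was 0.36. Between temperatures the median of these probes differed by -1.26 in CS3527, with an exact permutation p of 0.0286 that was not adjusted, and by 0.43 in MG1363.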

How the results depend on the processing

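The common floor, the kept spots and the alternatives for probe classes were chosen after the data were seen. Of 427 values of named genes under other settings, 426 kept their direction and their side of the threshold, and no count of called genes left the range of 1.5 times except with the 2-fold threshold, which by its construction left 208 genes for the strains at 38 °C, 401 at 30 °C, 528 and 354 for temperature in MG1363 and CS3527, 210 for the interaction and 286 over both temperatures. The exception is llmg_0845 in the interaction with the common floor. Named genes were chosen as the largest called changes, so these values do not speak for called genes in general. For the interaction, 441 of the 617 called genes were called in the same direction under quantile scaling. Without 1 array the counts ran from 955 to 1036 for the strains at 38 °C, 1339 to 1508 at 30 °C, 1502 to 1642 and 1269 to 1421 for temperature in MG1363 and CS3527, 468 to 784 for the interaction and 1447 to 1610 over both temperatures, and no called gene changed sign. The lowest count for the interaction came without MG1363 at 38 °C replicate 3. The highest count for the interaction came without CS3527 at 30 °C replicate 1. Genes differing the same way between strains at both temperatures numbered 949 under quantile scaling and 735 to 898 without 1 array, against 814. Runs of neighbours at 38 °C numbered 136 with at least 3 genes, 28 with at least 6 and 14 with a 2-fold change, and at 30 °C 46 with at least 6 and 25 with a 2-fold change, as stricter or looser definitions give. Without 1 array they ran from 59 to 74 at 38 °C and from 103 to 119 at 30 °C.

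Quantile scaling shifted the median of all genes by -0.21 for temperature in MG1363 and by 0.11 for the interaction, and median scaling by -0.26 and -0.22 for temperature in MG1363 and CS3527. For temperature in MG1363 normexp shifted it by -0.17, the common floor by -0.18 and the authors' values by -0.20, which also shifted the interaction by 0.11. Under quantile scaling 1116 of the 1656 genes called for temperature in MG1363 were called in the same direction. Of 987 region means, 175 moved by more than the spread between arrays. None changed sign where most of the region's genes were called in its direction. Among the rest, that of llmg_0835 to llmg_0851 for temperature in MG1363 went from 0.10 to -0.83 under quantile scaling. The depth that limits these values is signal over background, since 40 genes in MG1363 and 14 in CS3527 at 30 °C had no probe well above it. Replicate numbers did not pair the arrays, as same-numbered arrays correlated in their deviations by -0.44 to 0.33, and the replicate block gave 1102, 1437, 1613, 1408, 581 and 1515 genes. The filter on dim genes removed none, so its absence tests nothing. The planned gene list tests were not run.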

Other observations

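The regions in this part were chosen after their values were seen, as was the count of departing probes, and the tests of the hypotheses were set before. The 6 genes of llmg_0485 to llmg_0490 were higher at 38 °C in both strains and lower in CS3527 at both temperatures, and all 6 were called in each of these comparisons. Their mean was -5.38 ± 0.04 (SD, n = 4) at 30 °C and -1.61 ± 0.06 (SD, n = 3) at 38 °C in MG1363, and -7.13 ± 0.03 and -3.32 ± 0.04 (SD, n = 4) in CS3527. The strains differed by -1.76 at 30 °C and -1.71 at 38 °C, and the rises were 3.77 in MG1363 and 3.81 in CS3527. Whether the rises were alike depended on the scaling. They were 3.36 and 2.66 under normexp and 3.39 and 2.15 with the common floor, and the interaction mean of 0.05 became -0.69 and -1.24, or 0.48 under quantile scaling. The strain difference at 30 °C was -1.02 under normexp and -0.37 with the floor. The floor, at -5.43, lay above the CS3527 mean at 30 °C and just below that of MG1363. It thus cuts the rise in CS3527 and the strain difference at 30 °C by construction, and its values do not show unlike rises.

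The 4 genes of llmg_1529 to llmg_1532 were higher at 38 °C in MG1363, -4.54 ± 0.58 (SD, n = 3) against -7.86 ± 0.20 (SD, n = 4), while CS3527 stood at -7.60 ± 0.27 and -7.61 ± 0.36 (SD, n = 4). All 4 were called in the interaction, with a mean of -3.31 that was -1.02 with the common floor and between -1.92 and -3.27 under the other scalings. The 12 genes of llmg_2527 to llmg_2538 were higher in CS3527 by 2.07 at 30 °C and by 0.82 at 38 °C, with 12 called at each temperature and 11 called in the interaction. With the common floor these differences were 0.90 and 0.76, and the interaction mean went from -1.25 to -0.15, or to -0.66 with the authors' values. The floor lay above the mean of llmg_2527 to llmg_2538 in MG1363 at 30 °C. For llmg_1529 to llmg_1532 it lay above every group mean except that of MG1363 at 38 °C. Its values are thus shrunk by construction.

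One hypothesis was that CS3527 at 30 °C is shifted towards MG1363 at 38 °C. The strain difference at 30 °C and the temperature difference in MG1363 share the 4 MG1363 arrays at 30 °C. Across genes they correlated with r of 0.13 (covariance 0.10), where unchanged groups simulated on shared arrays gave a covariance of 0.01 and r of 0.46. Lists of these lengths would share 393.7 higher genes if independent, and 474 were shared, and 143 lower genes were shared where 130.3 would be. The shared arrays alone push both overlaps up, so no shared effect is read from them. With the shared arrays split between the comparisons the mean r was 0.12, but it was -0.10 under quantile scaling, so these values speak against a shift that holds across scalings.

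A second hypothesis was that CS3527 at 38 °C, relative to MG1363 at 38 °C, is shifted towards its own state at 30 °C. The comparisons share the 4 CS3527 arrays at 38 °C. The strain difference at 38 °C and the temperature difference in CS3527 had a mean split r of -0.14 under the main scaling and -0.16 under quantile scaling. Both lie between the bounds of -0.1 and -0.2 set beforehand and leave the hypothesis undecided. The unsplit r was -0.13 with a covariance of -0.07, where simulated unchanged groups gave 0.46 and 0.01. Of genes called in both, 314 were lower in CS3527 than MG1363 and higher at 38 °C, where 218.0 would be shared by independent lists, a value that leaves out the shared arrays.

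Among 12081 probes of genes with 4 or more probes, 1 departed from its gene's median strain difference by more than 1.5 log2 units in the same direction at both temperatures. This probe of llmg_0609 differed from the gene's median by -1.80 at 30 °C and by -1.54 at 38 °C, and no probe departed in opposite directions.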
